A study of Mus musculus with 4 samples.

How the data were processed

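RNA of 4 ATDC5 cell samples was hybridised to 1-colour whole-transcript arrays, 1 array per sample, after labelling with biotin, per the labels' protocols. The labels place 2 samples at day 0, before differentiation, and 2 at day 15, after 15 days with insulin, transferrin and selenite, and they number the samples of each day 1 and 2. The table the authors deposited holds 1 processed intensity per probe set and sample on a linear scale, judged from the values, which are never negative, have 2 decimals and reach 23103. The background correction, the summarization of probes and the normalization between arrays behind these intensities are not given in the sources used here. Per the submitters' processing notes the genome build was mm9. The gene table used for names is of assembly GRCm38.p6, so no coordinates are printed. No detection call or background flag was used, so dim values may lie at background.

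The table has 35512 probe sets. The platform annotation pairs 21789 of them with 1 gene symbol, 1621 with several and lists no gene for 12102. Probe sets with several symbols or none were left out of the tests of genes. The gene identifiers of 21698 of the 21789 were found in the gene table, and the other probe sets kept the symbol of the annotation. For a gene with more than 1 probe set (999 genes) the brightest over all 4 arrays was used, which left 19938 genes. Intensities were turned to log2 after adding 1. The arrays' medians differed by up to 0.20 log2, above the tolerance of 0.1 set in advance, so the log2 values of all probe sets were quantile normalized. A difference in log2 is on this scale of log2 intensity plus 1, on which background light and the added 1 make the change of dim genes look smaller.

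Day 15 was compared with day 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on all 4 arrays, with group as the only term), and genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes were called. Errors marked SE are limma's moderated standard errors of the difference, and SD is the spread of 2 arrays. For 28 gene lists the shift against all other genes was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists, and the members past an adjustment over the list alone were counted. Camera with a correlation estimated per list and fry were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom of the 4 arrays, so it has little power here. A call lost there does not show that correlation between genes made the shift. In the text an adjusted p given for a list is camera's, and one given for a gene is limma's. Some list members were not matched to a tested gene and are not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

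The groups, tests, gene lists, most alternatives and the rule for genes named in the text were fixed before the data were examined. The rule takes the 12 largest increases and the 12 largest decreases among called genes whose higher group mean is at or above the median of all genes and whose day 15 arrays both lie on the same side of both day 0 arrays, leaving out gene models without a proper symbol. It always takes Sox9, Col2a1, Acan, Col10a1, Runx2, Alpl, Mki67, Top2a, Tet1, Tet2, Tet3, Dnmt1, Dnmt3a and Uhrf1, of which Runx2 was not analysed here. From each list it takes up to 4 called members with the largest difference, or the 2 members with the largest difference where fewer than 2 were called. Other called members of the cartilage and hypertrophy lists, the genes Col9a3, Cnmd, Matn3, Irf1 and Mx1, which were not called, the markers C1qb, Csf1r, Acp5, Oscar, Dcstamp and Calcr, and the genes of the closing observations were named after their values were seen. Of the 342 called genes 8 were gene models without a proper symbol, and 1 of these, 1700010H22Rik (4.92 log2), would have been among the largest increases.

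The test was run on simulated data with the real genes' means and the fitted spreads, for day 15 against day 0 with 2 arrays each over 19938 genes, with 50 genes changed at each size. It recovered 2% of changes of 1 log2, 94% of 2, 96% of 3 and 98% of 4, and 4.6% of the calls were unchanged genes. Camera found a simulated list shifted by 0.5 log2, and 4% of unshifted lists had a p below 0.05. The simulated genes varied independently of each other, so that 4% may not hold for lists of correlated genes.

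The alternatives were the deposited scaling without quantile normalization, centring each array on its median, an intensity trend with robust hyperparameters, a filter to genes at or above the median level, the replicate number as a block, the mean of all probe sets of a gene, leaving out each array in turn, testing all probe sets together, a test against a difference of 0.5 log2 (treat) and a size threshold of 4-fold. Quantile normalization over named probe sets only, a pseudocount of 16 and leaving out genes at least 1 log2 higher in replicate 1 on both days were added after the data were seen. The replicate numbers are shared between days, but the labels do not say that a number marks a shared culture or batch. Across genes, replicate 1 minus replicate 2 correlated at 0.40 between the days. On both days 68 genes were at least 1 log2 higher in replicate 1 and 40 at least 1 log2 lower. Something was thus shared within a number, but 2 pairs are too few to tell what it was. The main test has no term for it.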

Results

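Gene expression was measured in ATDC5 cells, a mouse chondroprogenitor line that forms cartilage-like matrix in culture. Cells kept in basal medium with ascorbic acid were the day 0 group, and cells given insulin, transferrin and selenite for 15 days were the day 15 group. Each group had 2 arrays, and each array measured the total RNA of 1 sample on a whole-transcript oligonucleotide array. The deposited values were linear probe set intensities between 0.72 and 23103. On the log2 scale the median of all probe sets was 7.87 and 7.99 on the day 0 arrays and 7.88 and 8.06 on the day 15 arrays. After quantile normalization, the arrays of 1 group correlated across genes at 0.984 for day 0 and 0.983 for day 15. Arrays of different days correlated at 0.962 to 0.973. By the median absolute log2 difference, however, the closest arrays were those of replicate 2 on the different days (0.187). The day 0 pair differed by 0.199, the day 15 pair by 0.224 and the replicate 1 arrays of the different days by 0.217. For the typical gene the arrays were thus not grouped clearly by day. The genes behind these values are not independent replicates. The number of arrays limits the precision of every value. The labels do not say that the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

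The comparison of day 15 with day 0 asked how the expression profile changes over 15 days with insulin, transferrin and selenite. Neither group held cells cultured for 15 days without them. Effects of time in culture, of the supplement and of differentiation can therefore not be told apart here. The largest increases included genes of cartilage and of mineralizing matrix. Hapln1, the link protein that holds aggrecan on hyaluronan (probe set 10406519), rose from 6.77 ± 0.07 to 12.91 ± 0.02 (log2 intensity, SD, n = 2 arrays per group), which is 70.5-fold. Ibsp, the bone sialoprotein of mineralized matrix, rose 41.1-fold, C1qtnf3, a secreted protein of cartilage, rose 45.1-fold and Prss35, a serine protease homologue, rose 51.6-fold. Frzb, a secreted Wnt antagonist first found in cartilage, rose 33.0-fold. The largest decreases were smaller. Fosl1, a subunit of the transcription factor AP-1, fell by 3.02 on the log2 scale, and Pappa, a protease that cleaves insulin-like growth factor binding proteins, fell by 2.91.

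Of 19938 genes tested with limma, 342 had an adjusted p below 0.05, of which 260 were higher and 82 lower at day 15. All 342 differed by at least 2-fold, and 163 by at least 4-fold (139 higher, 24 lower). The smallest difference called was 1.04 log2, and the median within-group SD of all genes was 0.18 log2. The other genes among the 12 largest increases were Ly6a2 (5.00 log2), the connexin Gjc3 (4.83), the peptidylarginine deiminase Padi2 (4.36), the channel protein Panx3 (4.34), the sodium-calcium exchanger Slc8a3 (4.31), the ribonuclease Rnase2a (4.29) and the guanylate-binding protein Gbp8 (4.28). The other genes among the 12 largest decreases were Prl2c5 of the prolactin family (−3.32 log2), the sialic acid-binding lectin Siglecg (−3.26), S100a7a (−3.18), Nlrp2 (−2.86), Rnf39 (−2.77), the potassium channel subunit Kcnf1 (−2.75), the transcription factor Atoh8 (−2.57), the kinase Styk1 (−2.49), Prss46 (−2.43) and the cytokine Il7 (−2.40). Across these 24 genes the limma adjusted p ran from 0.000606 for Hapln1 to 0.0287 for Il7. Ly6a2, Rnase2a, Gbp8 and Prl2c5 belong to families of similar genes, and whether their probe sets tell the members apart was not examined. The count was 174 without day 15 replicate 1 and 196 without day 15 replicate 2, the number lower was 46 without day 0 replicate 2, and 74 probe sets passed when all 35512 were tested together. Among the genes named above, limma adjusted p passed 0.05 without day 15 replicate 1 for Prl2c5 (0.0685), Fosl1 (0.0631), Pappa (0.0565) and Atoh8 (0.0619), without day 15 replicate 2 for Padi2 (0.0511), Fosl1 (0.0505), Rnf39 (0.0513), Atoh8 (0.0586), Prss46 (0.0612) and Il7 (0.0513), and without day 0 replicate 2 for Il7 (0.0591); in these fits the lone sample of a day is assumed to vary like the other day's pair.

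**Figure D1:**
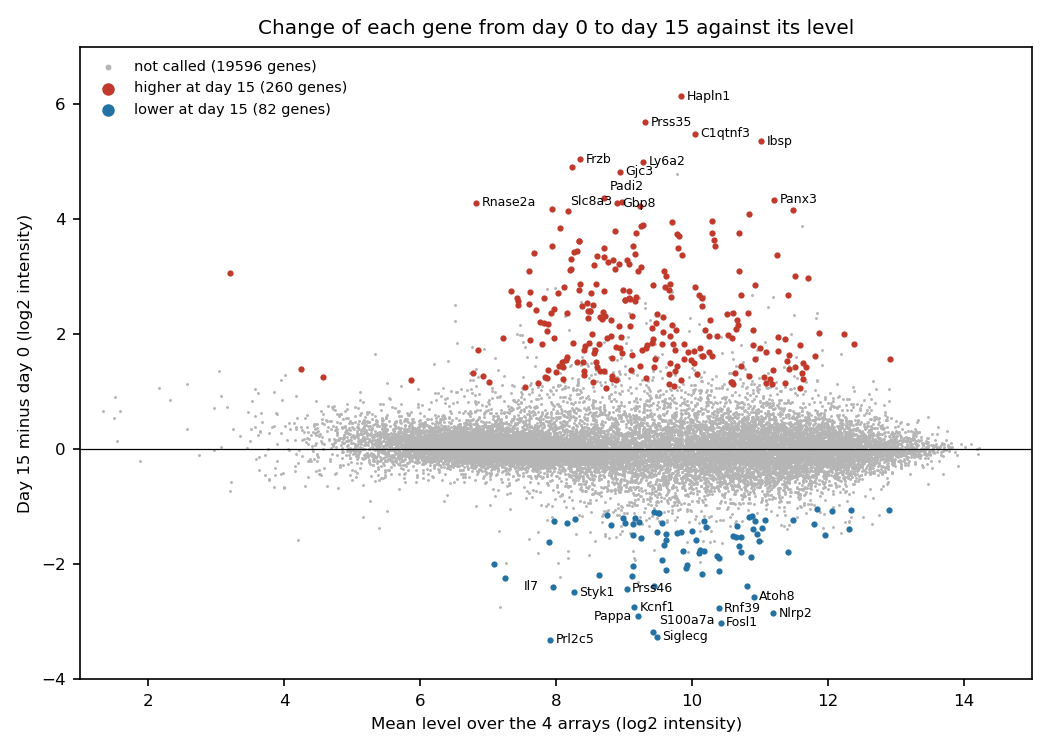
Day 15 minus day 0 (log2 intensity) against the mean level over the 4 arrays (log2 intensity), 1 point per gene. The 260 genes called higher (red) reach 6.14 log2 at Hapln1 and the 82 called lower (blue) reach −3.32 log2 at Prl2c5; grey points were not called, and the named points are the 12 largest increases and 12 largest decreases.

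Of 25 measured genes of the cartilage extracellular matrix 7 rose. Besides Hapln1, Ucma, a small protein of the growth plate, rose by 4.17 ± 0.33 log2 (SE), and Fmod, a small leucine-rich proteoglycan that binds collagen, rose by 3.63 ± 0.39. Acan, the core protein of the main cartilage proteoglycan aggrecan (probe set 10554249), rose 11.6-fold from 7.36 ± 0.20 to 10.89 ± 0.94 (log2 intensity, SD, n = 2). Col2a1, which encodes type II collagen (probe set 10432045), rose by 2.17 ± 0.33 log2 (SE) from 9.59 ± 0.14 to 11.76 ± 0.68. None fell and 18 were not called by the limma test over all genes, among them Col9a3 (−0.06 log2), Cnmd (−0.11) and Matn3 (−0.13), and adjusted over the list alone 11 were higher and none lower; Matn1 and Col11a1 were the other 2 of the 7. The list as a whole was shifted up by a mean of 1.34 log2 (limma camera adjusted p = 8.94e-11; adjusted p = 0.447 with an estimated correlation). Acan and Col2a1 were both higher in day 15 replicate 2 than in replicate 1, at 11.56 against 10.22 for Acan. The call of Col2a1 (limma adjusted p = 0.0441) was lost without day 0 replicate 1 (0.0678), without day 0 replicate 2 (0.105), without day 15 replicate 2 (0.0513) and with quantile normalization over named probe sets (0.0508), and that of Fmod without day 15 replicate 2 (0.059).

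Genes of chondrocyte hypertrophy and mineralization showed the highest median change of the lists, 1.87 log2. Col10a1, the type X collagen of hypertrophic chondrocytes (probe set 10362495), rose 15.0-fold from 7.32 ± 0.46 to 11.23 ± 0.06 (log2 intensity, SD, n = 2). Panx3 rose 20.2-fold and Pth1r, the receptor of parathyroid hormone and its related peptide, rose 6.45-fold. Of 17 measured members 6 rose and none fell, and adjusted over the list alone 10 rose and 1 fell. Mef2c, a transcription factor of hypertrophy, and Mgp, an inhibitor of mineralization, were the remaining called members. Alpl, the alkaline phosphatase of mineralizing cells, was already bright at day 0 and its values were 12.83 ± 0.08 at day 0 and 13.15 ± 0.24 at day 15, which did not pass the test (limma adjusted p = 0.640). The list was shifted up by a mean of 1.81 log2 (limma camera adjusted p = 8.94e-11; adjusted p = 0.447 with an estimated correlation). Spp1, Bglap, Enpp1 and Runx2 of this list were not analysed here.

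**Figure D2:**
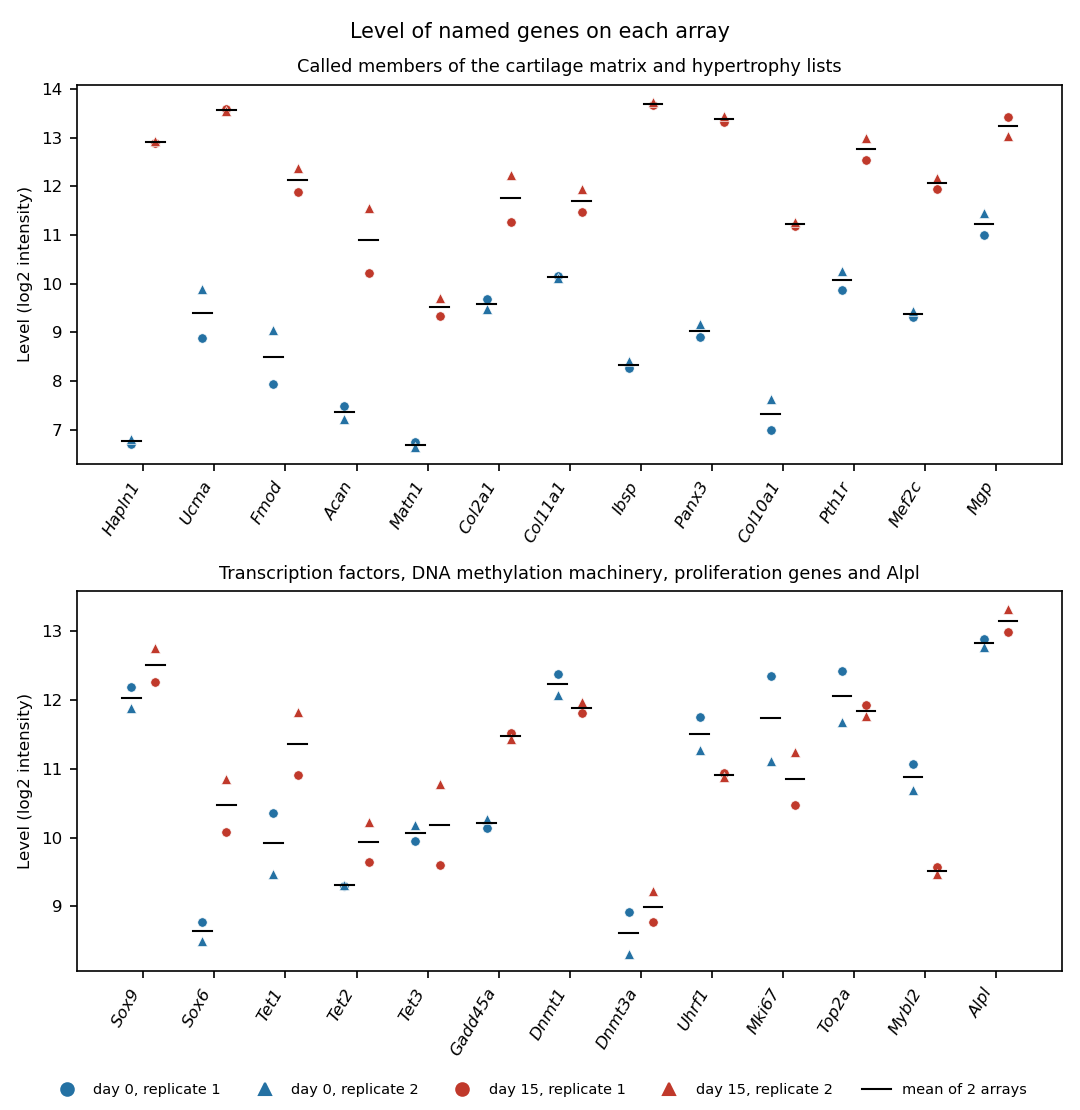
Level on each array (log2 intensity) of the called cartilage and hypertrophy genes, above, and of transcription factors, DNA methylation genes, proliferation genes and Alpl, below; points are arrays and bars are means of 2 arrays. Hapln1 lies near 6.77 on both day 0 arrays and near 12.91 on both day 15 arrays, while the arrays of 1 day differ by more for Tet1 and Mki67.

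Enzymes that build and sulfate glycosaminoglycans included 2 genes that rose out of 29 measured. Xylt1, which starts the glycosaminoglycan chain, rose 5.15-fold, and Csgalnact1, which starts chondroitin sulfate, rose 3.44-fold. Adjusted over the list alone 4 rose and 1 fell. The list's mean was 0.32 log2 (limma camera adjusted p = 0.0398; adjusted p = 0.447 with an estimated correlation), and the call was lost without day 0 replicate 1 (0.0726), without day 15 replicate 2 (0.101) and, with all 4 arrays, with trend and robust hyperparameters (0.0682). Xylt1 lost its call without day 0 replicate 2 (0.0577) and day 15 replicate 2 (0.0524), and Csgalnact1 without day 0 replicate 2 (0.0677), day 15 replicate 1 (0.0773) and day 15 replicate 2 (0.0928). Among genes that process and secrete collagen, Pcolce2, an enhancer of procollagen C-proteinase, rose by 1.39 ± 0.20 log2 (SE) as the only one of 31 measured members called over all genes. P3h3, a prolyl hydroxylase, was 10.47 ± 0.04 at day 0 and 11.40 ± 0.22 at day 15, which did not pass (limma adjusted p = 0.101), although it passed adjusted over the list alone, where 2 members were higher and none lower. This list's mean was 0.25 log2 (limma camera adjusted p = 0.0046; adjusted p = 0.484 with an estimated correlation). The call was lost without day 0 replicate 2 (0.135) and without day 15 replicate 2 (0.0617), and Pcolce2 lost its call without day 0 replicate 2 (0.13), day 15 replicate 1 (0.112) and day 15 replicate 2 (0.126), and with median centring (0.0505). None of the 28 matrix proteases and inhibitors passed over all genes with limma, 8 had an unadjusted p below 0.05, and adjusted over the list alone 2 were higher and none lower. The largest differences there were 1.84 ± 0.38 log2 (SE) for Adamts4 and 1.22 ± 0.25 for Adamts9, both aggrecan- or versican-cleaving proteases (limma adjusted p = 0.107 and 0.112; Adamts4 was called, at 2.39 log2, without day 0 replicate 1, 0.0112), and the list was not shifted (limma camera adjusted p = 0.215).

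Transcription factors of chondrogenesis went both ways. Sox6, a partner of Sox9 in cartilage, rose by 1.83 ± 0.29 log2 (SE) and Sox8 by 1.06 ± 0.17. Twist2 fell by 1.29 and Msx2 fell by 1.11 on the log2 scale, both factors of less differentiated mesenchyme. Sox9, the main factor of the chondrocyte lineage, was at 12.03 ± 0.22 at day 0 and 12.50 ± 0.35 at day 15 (log2 intensity, SD, n = 2), a difference that did not pass (limma adjusted p = 0.533). Of 26 measured members 2 rose, 2 fell and 22 were not called, with the same numbers adjusted over the list alone, and the list was not shifted (limma camera adjusted p = 0.834). The call of Sox6 (limma adjusted p = 0.0498) was lost without day 0 replicate 1 (0.0721), without day 0 replicate 2 (0.132), without day 15 replicate 2 (0.0814) and on the deposited scaling (0.0502). When any 1 of the 4 arrays was left out, the calls of Twist2 (0.0916 to 0.0949), Msx2 (0.125 to 0.159) and Sox8 (0.133 to 0.195) were lost. The deposited scaling, median centring and the trend and robust setting ended the calls of Msx2 (0.0507, 0.0537 and 0.0588) and Sox8 (0.056, 0.0571 and 0.0542), and quantile normalization over named probe sets those of Sox6 (0.0625) and Sox8 (0.0605).

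Inhibitory Smads fell while several Wnt pathway genes rose. Smad6 and Smad7, which block receptor signaling of the BMP and TGF-beta family, fell by 1.47 and fell by 1.79 on the log2 scale, and Smad9, a BMP receptor-regulated Smad, fell by 2.07. Bambi, a decoy receptor of the same pathway, rose by 1.23 ± 0.20 (SE). Thus 1 of 34 BMP and TGF-beta genes rose and 3 fell (3 and 5 adjusted over the list alone), with no shift of the list (limma camera adjusted p = 0.341). In the Wnt list 4 of 31 measured genes rose and none fell (5 and 0 adjusted over the list alone). They were Frzb, the secreted inhibitor Wif1 (2.85 ± 0.20 log2), the ligand Wnt5a (1.99 ± 0.29) and the receptor Fzd9 (1.68 ± 0.17). Frzb and Wif1 are antagonists of the pathway. The Wnt list was shifted up by a mean of 0.52 log2 (limma camera adjusted p = 0.000577; adjusted p = 0.447 with an estimated correlation). Of 23 measured hedgehog and FGF genes, Fgfr3, a receptor of growth plate chondrocytes, rose 3.22-fold and Spry1, a feedback inhibitor of receptor signaling, rose 2.95-fold. None fell over all genes, 2 were higher and 1 lower adjusted over the list alone, and the list was not shifted (limma camera adjusted p = 0.717). Calls were lost without day 15 replicate 1 for Smad9 (0.122), Smad7 (0.178), Wnt5a (0.145), Fzd9 (0.0512) and Spry1 (0.121), and without day 15 replicate 2 for Smad9 (0.0786), Smad7 (0.112), Wnt5a (0.102), Fzd9 (0.0538), Fgfr3 (0.0704) and Spry1 (0.107). Calls were also lost without day 0 replicate 1 for Fgfr3 (0.0693) and Spry1 (0.0793), without day 0 replicate 2 for Smad7 (0.0855) and Wnt5a (0.051), and without any 1 of the 4 arrays for Smad6 (0.0533 to 0.126) and Bambi (0.083 to 0.151). The deposited scaling and quantile normalization over named probe sets ended the calls of Smad7 (0.0587 and 0.054) and Bambi (0.0537 and 0.0585), and median centring that of Wnt5a (0.0505).

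Among genes tied to the supplement given, Igfbp4, a binding protein of insulin-like growth factors, rose 17.0-fold from 8.79 ± 0.67 to 12.87 ± 0.05 (log2 intensity, SD, n = 2). Pappa, the protease that cleaves Igfbp4, fell by 2.91 on the log2 scale, from 10.66 ± 0.57 to 7.75 ± 0.07. The other 21 of the 23 insulin and IGF genes were not called over all genes, 6 were higher and 4 lower adjusted over the list alone, and the list was not shifted (limma camera adjusted p = 0.269). Of 28 iron and selenoprotein genes 3 rose and none fell (5 and 1 adjusted over the list alone; limma camera adjusted p = 0.0929). Slc40a1, the iron exporter ferroportin, rose 11.3-fold, Selenop, a secreted selenium carrier, rose 4.23-fold, and Selenow, a small selenoprotein, rose 2.70-fold. Pappa lost its call without day 15 replicate 1 (limma adjusted p = 0.0565), Selenop without day 15 replicate 1 (0.0821) and day 15 replicate 2 (0.0742), and Selenow without any 1 of the 4 arrays (0.0578 to 0.0783). The iron and selenoprotein list was called, with a mean of 0.31 log2, without day 0 replicate 2 (0.0415), and with all 4 arrays it was called with trend and robust hyperparameters (0.0379) and with quantile normalization over named probe sets (0.0284).

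Because the series as a whole concerns hydroxymethylcytosine and gene activation, the genes that write, remove and read DNA methylation were compared as 1 list. Gadd45a, a stress-response gene linked to active demethylation, rose by 1.27 ± 0.17 log2 (SE), from 10.21 ± 0.09 to 11.48 ± 0.07 (SD, n = 2). Tet1, a dioxygenase that makes hydroxymethylcytosine (probe set 10369702), was at 9.92 ± 0.63 at day 0 and 11.36 ± 0.65 at day 15. Its difference of 1.45 ± 0.41 log2 (SE) did not pass (limma adjusted p = 0.223), and its 3 probe sets gave 1.39, 1.41 and 1.45. Tet2 differed by 0.63 ± 0.24 log2 (limma adjusted p = 0.367) and Tet3 by 0.13 ± 0.38 (limma adjusted p = 0.977). The maintenance methyltransferase Dnmt1 differed by −0.34 ± 0.19 log2 (limma adjusted p = 0.60), its cofactor Uhrf1 by −0.60 ± 0.21 (0.333) and the de novo methyltransferase Dnmt3a by 0.39 ± 0.27 (0.727). Of 25 measured genes only Gadd45a was called over all genes, 2 were higher and none lower adjusted over the list alone, and the list was not shifted (limma camera adjusted p = 0.682). Gadd45a lost its call when any 1 of the 4 arrays was left out (limma adjusted p = 0.0841 to 0.121).

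Genes of the cell cycle and DNA replication were lower at day 15 as a list, by a mean of 0.39 log2 (limma camera adjusted p = 2.19e-08; adjusted p = 0.551 with an estimated correlation). Mybl2, a transcription factor of proliferating cells, fell by 1.36 on the log2 scale, from 10.88 ± 0.27 to 9.52 ± 0.07 (SD, n = 2), and was the only called gene of 51 measured. Mcm10, a replication factor, was at 10.85 ± 0.25 and 9.69 ± 0.41 (limma adjusted p = 0.13). The proliferation marker Mki67 was at 12.35 and 11.11 on the day 0 arrays and at 10.48 and 11.24 on the day 15 arrays, so the days overlapped (limma adjusted p = 0.562). Top2a, a topoisomerase of dividing cells, was at 12.05 ± 0.53 and 11.84 ± 0.11 (limma adjusted p = 0.899), while its dimmer probe set differed by −2.18 log2. A negative difference was found for 46 of the 51 genes, and none was higher and 2 were lower adjusted over the list alone. The list's median difference was −0.50 log2 between the replicate 1 arrays and −0.18 between the replicate 2 arrays. Its mean was −0.13 log2 without day 0 replicate 1 and −0.65 without day 0 replicate 2, and Mybl2 lost its call when any 1 of the 4 arrays was left out (0.051 to 0.129) and with median centring (0.0632).

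Genes of cell cycle arrest were higher as a list, by a mean of 0.66 log2 (limma camera adjusted p = 4.23e-06; adjusted p = 0.484 with an estimated correlation). Gas6, a growth arrest-specific ligand, rose by 1.16 ± 0.18 log2 (SE) and was the only 1 of 18 measured that was called. Plagl1, a zinc finger inhibitor of growth, was at 10.10 ± 0.24 and 11.82 ± 0.76 (SD, n = 2), and the cyclin-dependent kinase inhibitor Cdkn1c at 7.98 ± 0.71 and 9.58 ± 0.08 (limma adjusted p = 0.121 and 0.114). Adjusted over the list alone 5 were higher and none lower. Gas6 lost its call when any 1 of the 4 arrays was left out (0.0988 to 0.17) and with quantile normalization over named probe sets (0.0512). Cdkn1c was called without day 0 replicate 1 (0.0155) and Plagl1 without day 15 replicate 1 (0.0335), and Cdkn1a was not analysed here.

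Of 29 measured genes of glycolysis and hypoxia 2 rose. Egln3, an oxygen-sensing prolyl hydroxylase that hypoxia induces, rose 4.61-fold, and Car9, a hypoxia-induced carbonic anhydrase, rose 2.24-fold. None fell, 7 were higher and 1 lower adjusted over the list alone, and the list mean was 0.48 log2 (limma camera adjusted p = 8.14e-06; adjusted p = 0.447 with an estimated correlation). Both are oxygen-response genes, and no enzyme of glycolysis in the list was called over all genes. None of the 27 measured genes of cholesterol and fatty acid synthesis passed with limma, over all genes or adjusted over the list alone, 1 had an unadjusted p below 0.05, and 23 had a negative difference. Fasn, the fatty acid synthase, differed by −0.74 ± 0.37 log2 (SE) and Mvd, an enzyme of the mevalonate pathway, by −0.64 ± 0.29. The list mean was −0.24 log2 (limma camera adjusted p = 0.00103; adjusted p = 0.585 with an estimated correlation), and it was −0.07 without day 0 replicate 1 (0.301) and −0.41 without day 0 replicate 2. Car9 lost its call when any 1 of the 4 arrays was left out (limma adjusted p = 0.09 to 0.159), on the deposited scaling (0.0718), with median centring (0.0524) and with quantile normalization over named probe sets (0.0603).

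Of 25 measured interferon and antiviral genes 4 rose. Usp18 rose 3.78-fold, Ifit3 3.52-fold, Oasl2 3.41-fold and Ifit1 3.22-fold, all of them genes that type I interferon induces. None fell, 21 were not called, among them Irf1 (−0.28 log2) and Mx1 (−0.05), and 9 were higher adjusted over the list alone. The mean was 0.62 log2 (limma camera adjusted p = 2.61e-06; adjusted p = 0.447 with an estimated correlation), and the median was 0.53 log2 between the replicate 1 arrays and 0.29 between the replicate 2 arrays. Without day 15 replicate 1 all 4 calls were lost, at a limma adjusted p of 0.106 for Usp18, 0.0513 for Ifit3, 0.0643 for Oasl2 and 0.0687 for Ifit1, and without day 0 replicate 2 those of Usp18 (0.0562), Oasl2 (0.0585) and Ifit1 (0.0624), while Usp18 was also lost without day 0 replicate 1 (0.0929) and with median centring (0.0512). Inflammatory cytokine and acute response genes were lower as a list, by a mean of 0.27 log2 (limma camera adjusted p = 0.00723; adjusted p = 0.447 with an estimated correlation), a call lost without day 15 replicate 2 (−0.16 log2, 0.101). None of 27 measured genes was called by limma over all genes, with 9 at an unadjusted p below 0.05 and 6 lower adjusted over the list alone. Ptgs2, the inducible cyclooxygenase, differed by −1.26 ± 0.27 log2 (SE) and the chemokine Ccl7 by −1.25 ± 0.37 (limma adjusted p = 0.118 and 0.242; Ptgs2 was called with trend and robust hyperparameters, 0.0444). In the list of the unfolded protein and amino acid response none of 30 genes was called by limma over all genes, 3 had an unadjusted p below 0.05 and 1 was higher adjusted over the list alone. Ddit4, a stress-induced inhibitor of mTOR, differed by 1.23 ± 0.35 log2 and the stress transcription factor Ddit3 by 0.95 ± 0.16 (limma adjusted p = 0.221 and 0.0634), with no shift of the list called (limma camera adjusted p = 0.154). Ddit4 was called without day 0 replicate 1 (0.0296), and the list, with a mean of 0.17 log2, with quantile normalization over named probe sets (0.0345).

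**Figure D3:**
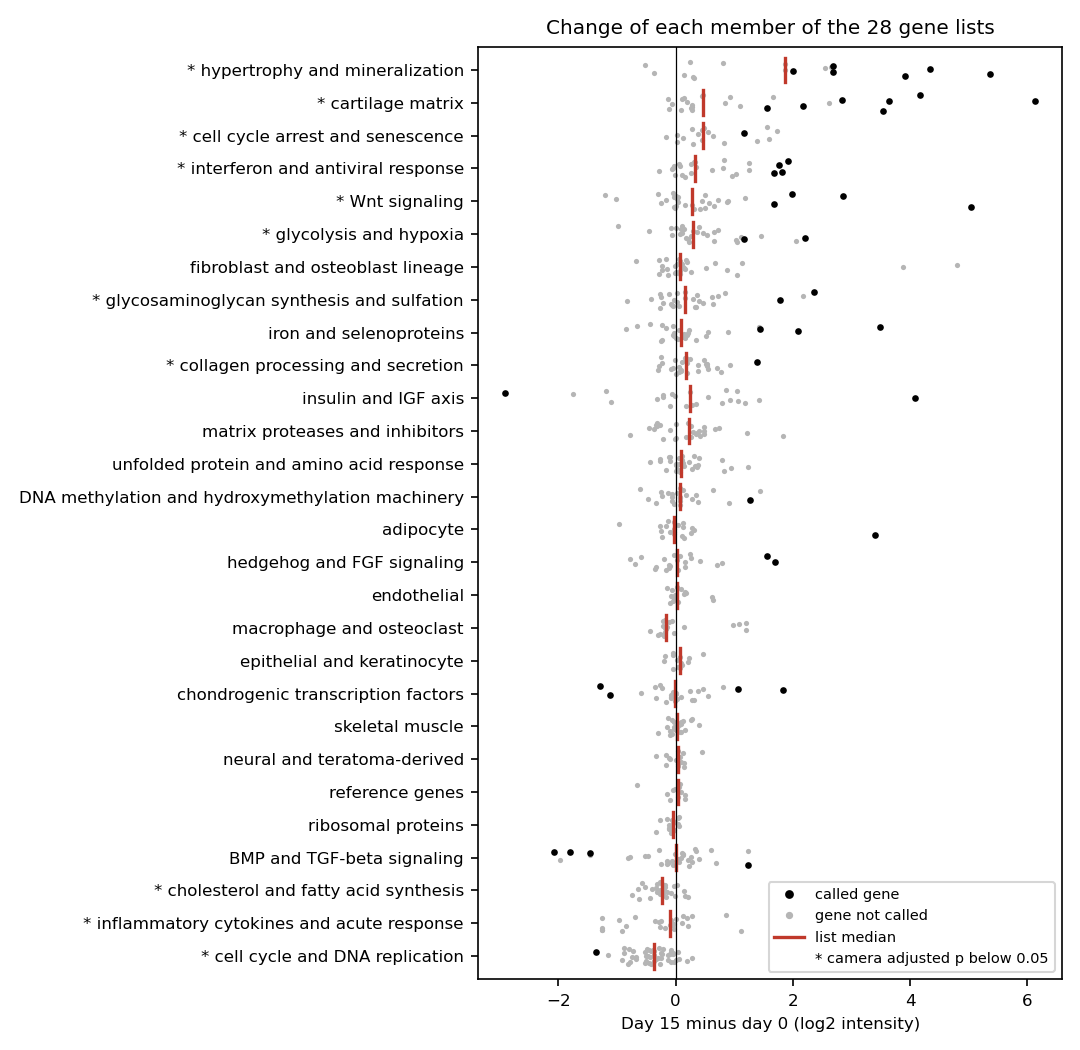
Day 15 minus day 0 (log2 intensity) of every measured member of the 28 gene lists, with lists ordered by their mean; black points are called genes, grey points are genes not called and the red bar is the list median. The hypertrophy list has the highest median, 1.87 log2, and the cell cycle list the lowest, −0.37 log2; a star marks the 11 lists with a camera adjusted p below 0.05.

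Markers of other cell types were mostly not called. Of 33 measured fibroblast and osteoblast genes none passed over all genes with limma, and 5 had an unadjusted p below 0.05. The small proteoglycans Lum and Dcn were far apart on the day 0 arrays, Lum at 5.78 and 8.97 and Dcn at 8.10 and 11.27, and high on both day 15 arrays, at 12.22 and 12.12 for Lum and 13.65 and 13.47 for Dcn. Their differences of 4.80 and 3.88 log2 did not pass with all arrays (limma adjusted p = 0.0974 and 0.164). Without day 0 replicate 1 both were called, Lum at 3.18 log2 (0.00432) and Dcn at 2.29 (0.0122), and without day 0 replicate 2 as well, Lum at 6.43 (0.00134) and Dcn at 5.47 (0.00142). In the list 2 members were higher adjusted over the list alone, and the list was not shifted (limma camera adjusted p = 0.212), but it was called, with a mean of 0.40 log2, without day 15 replicate 1 (0.041). Of 20 adipocyte genes, the carbonic anhydrase Car3 rose 10.6-fold, and the adipogenic regulator Pparg was at 11.57 ± 0.15 and 10.60 ± 0.01 (SD, n = 2; limma adjusted p = 0.0695). Adjusted over the list alone 1 was higher and 1 lower, and the list was not shifted (limma camera adjusted p = 0.834). No gene was called by limma, over all genes or adjusted over the list alone, among 24 skeletal muscle, 15 endothelial, 15 epithelial, 15 neural and teratoma-derived, 18 ribosomal protein and 11 reference genes. The 2 largest differences in each were 0.41 for Mylpf and −0.30 for Cav3 in muscle, 0.64 for Emcn and 0.61 for Erg in endothelium, 0.46 for Perp and 0.22 for Krt19 in epithelium, 0.45 for Tubb3 and −0.33 for Pou5f1 in the neural list, −0.34 for Rpl13 and −0.26 for Rps19, and −0.66 for Tfrc and 0.17 for B2m among reference genes, all in log2. Their limma camera adjusted p values were 0.843, 0.686, 0.834, 0.981, 0.245 and 0.834 in that order, and 0, 2, 0, 1, 0 and 0 of their genes had an unadjusted p below 0.05.

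Several macrophage markers differed by replicate number on both days, while the osteoclast genes Acp5, Oscar, Dcstamp and Calcr differed by at most 0.43 log2 in size. These osteoclast genes lay at 6.62 to 7.74 log2 on the arrays, below the median level of all genes (8.72), and dim genes may show less change. C1qb, a complement subunit made by macrophages, was at 11.36 and 11.11 on the replicate 1 arrays of day 0 and day 15 and at 6.09 and 5.80 on the replicate 2 arrays. Csf1r, the receptor that macrophages need, was at 10.31 and 10.19 against 6.71 and 6.49. Replicate 1 exceeded replicate 2 by a median of 1.58 log2 at day 0 and 1.49 log2 at day 15 over the 20 genes of the list, and 16 of the 20 were higher in replicate 1 on each day. Between days none of the 20 was called by limma over all genes or adjusted over the list alone, and 1 had an unadjusted p below 0.05. Cd68 differed by 1.20 ± 0.59 log2 (SE) and Lyz2 by 1.20 ± 0.46 (limma adjusted p = 0.530 and 0.383), with Cd68 at 9.41 and 10.66 on the replicate 1 arrays and at 8.10 and 9.24 on the replicate 2 arrays. The median between days was −0.17 log2, at percentile 0.15 of 10000 random lists matched on level. The list was not shifted with all arrays (limma camera adjusted p = 0.834), and its mean was 0.99 log2 without day 0 replicate 1 (0.0134) and −0.82 without day 0 replicate 2 (0.00786), both of them called. In all, 68 genes were at least 1 log2 higher in replicate 1 on both days, and 40 were at least 1 log2 lower. None of either set was among the 342 called genes, and 1 of the 68 had an unadjusted p below 0.05. A gene picked for a gap within both days can hardly be called between them. The absence of calls therefore does not show that the replicate difference left the calls untouched. With these 68 left out, a choice made after seeing the data, 377 genes were called.

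**Figure D4:**
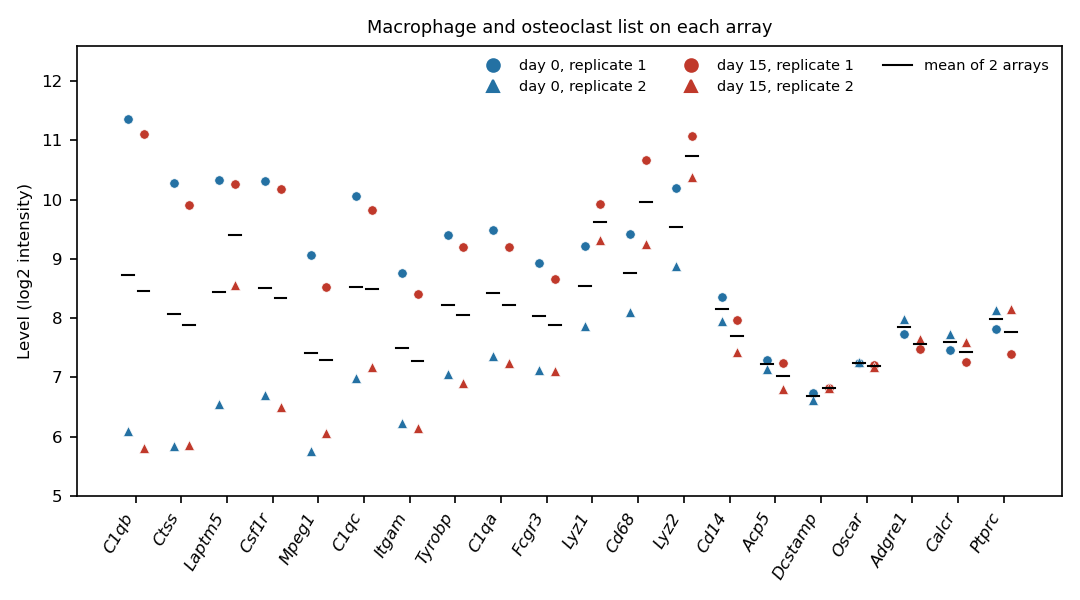
Level on each array (log2 intensity) of the 20 macrophage and osteoclast markers; points are arrays and bars are means of 2 arrays. C1qb lies at 11.36 and 11.11 on the replicate 1 arrays (circles) and at 6.09 and 5.80 on the replicate 2 arrays (triangles).

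The 11 list shifts named above rest on camera with a preset correlation of 0.01 between genes. None of the 11 held with an estimated correlation (camera adjusted p = 0.447 to 0.585), where 1 of the 28 lists had an unadjusted p below 0.05. The Wnt and glycosaminoglycan lists lost their calls too, though their estimated correlations (−0.027 and −0.033) were below the preset. With 2 residual degrees of freedom the losses may be of power, so they do not decide whether the 11 shifts hold. The directional test of fry called the glycosaminoglycan and Wnt lists, and its mixed test called 19 of the 28 lists. Median, mean and camera direction differed in sign for the transcription factor, BMP and TGF-beta, adipocyte, macrophage and reference gene lists, none of which was called.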

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

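Quantile normalization over named probe sets and the pseudocount of 16 were chosen after the data were seen. Changes of 1 log2 or less are mostly out of reach with 2 arrays per group, and without detection calls the signal over background is unknown. Among settings with all 4 arrays and all genes, the number of called genes was 313 on the deposited scaling, 320 with median centring, 451 with trend and robust hyperparameters, 343 with the mean of probe sets, 310 with quantile normalization over named probe sets and 356 with a pseudocount of 16; among genes at or above the median level it was 282. Of the called genes, none of the 60 that the naming rule takes changed direction under a setting in which it was tested. Testing all probe sets together called 74, of which 51 stood for genes among the 342; there the spread model gave 2.39 prior degrees of freedom in place of 3.79. The test against 0.5 log2 called 156, and a 4-fold threshold left 163. Leaving out 1 array, with the lone sample of a day assumed to vary like the other day's pair, gave 174 to 282 called genes, 145 to 219 higher, 29 to 63 lower and 174 to 282 at least 2-fold; the lowest total was without day 15 replicate 1, and 196 were called without day 15 replicate 2. Fewer samples lower the power of these fits. Of those 60 genes, 45, 39, 34 and 31 kept their call without day 0 replicate 1, day 0 replicate 2, day 15 replicate 1 and day 15 replicate 2. With all arrays, 6 lost it on the deposited scaling, 7 with median centring, 2 with trend and robust hyperparameters, 7 with quantile normalization over named probe sets and 25 in the test against 0.5 log2.

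With the replicate number as a block 628 genes were called (440 higher, 188 lower, 555 at least 2-fold), including all 342. Among the genes that rule takes 9 gained a call there, including Lum (limma adjusted p = 0.0449) and Cd68 (0.0233). Replicate 1 minus replicate 2 correlated at 0.40 between the days across genes, and the labels do not say what the number marks. The glycosaminoglycan list, with a mean of 0.32 log2, was no longer called under the block (limma camera adjusted p = 0.0669) nor with trend and robust hyperparameters (0.0682), and the cause was not tested.

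Of 28 lists 11 were called; 0 were with an estimated correlation, 2 by directional fry and 19 by mixed fry. The list means, which the estimated correlation leaves as they are, were 1.34 for cartilage matrix, 1.81 for hypertrophy, 0.32 for glycosaminoglycans, 0.25 for collagen processing, 0.52 for Wnt, −0.39 for cell cycle, 0.66 for arrest, 0.48 for glycolysis and hypoxia, −0.24 for cholesterol, 0.62 for interferon and −0.27 for inflammation. Leaving out 1 array gave means of 0.29 to 0.35 for glycosaminoglycans, 0.18 to 0.32 for collagen processing, −0.41 to −0.074 for cholesterol and −0.37 to −0.16 for inflammation, the lists that lost a call in such a fit. The macrophage list, not called with all arrays (mean 0.0859, camera direction down), was called higher without day 0 replicate 1 (0.99) and lower without day 0 replicate 2 (−0.82); its markers were higher on the replicate 1 arrays.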

Other observations

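The values of the genes named here were seen before they were grouped, and apart from limma's test of day 15 against day 0 the tests here were chosen after the results they address were seen; for the imprinted and ribosome biogenesis genes the outcome to look for was set down before the test was run. Of 7 guanylate-binding proteins, large GTPases that interferons induce, 4 rose at day 15, Gbp8 by 4.28 ± 0.23 log2 (SE), Gbp4 by 2.78 ± 0.17, Gbp9 by 2.68 ± 0.16 and Gbp11 by 1.94 ± 0.28 (n = 2 arrays per day), with limma adjusted p values of 0.00281, 0.00303, 0.00303 and 0.0379. Gbp3, Gbp5 and Gbp7 differed by 0.91, 0.92 and 0.98 log2 and did not pass (limma adjusted p = 0.255, 0.309 and 0.0969). The probe sets of this family may not tell its members apart. Nt5e, the ectonucleotidase that makes adenosine, rose by 2.25 ± 0.25 log2.

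Called genes were read for shared themes, and 4 themes were tested on other members, against 10000 random lists of the same size matched on mean level. These lists are drawn gene by gene and lack the correlation between genes of 1 process. Percentiles here and below may therefore overstate how unusual a list is. Between the arrays of 1 day, the cell cycle list lay at percentile 99.97 (day 15) and the YAP targets tested below at 4.82 (day 0). The ribosome biogenesis genes lay at 12.41 on day 0 and 88.25 on day 15. For ribosome biogenesis, after Mdn1, Utp20, Rrp12 and Heatr1 were seen to fall by 1.66, 1.44, 1.25 and 1.18 on the log2 scale, 36 other genes of the process had a median difference of −0.51 log2, at percentile 0. All 36 differences were negative, 21 had an unadjusted p below 0.05 and none was called by limma over all genes. The median was −0.35 log2 between the replicate 1 arrays and −0.59 between the replicate 2 arrays, which is consistent with a lower expression of these genes at day 15. For YAP, a growth and tension-sensitive coactivator, Ankrd1, Ajuba and Crim1 were seen to fall by 2.37, 1.69 and 1.79 log2. The targets Ccn1 (−0.26 log2), Ccn2 (−0.30) and Amotl2 (−1.01) had also been seen and were not called (limma adjusted p = 0.77, 0.88 and 0.083). Without all of these, 16 other target genes had a median of −0.44 log2, at percentile 0, which may reflect lower expression of the group. None of the 16 was called lower, Nt5e rose, 5 had an unadjusted p below 0.05, the median was −0.24 log2 between the replicate 1 arrays and −0.33 between the replicate 2 arrays, and 3 of the 16 are also in the lists fixed beforehand. Of 25 imprinted genes picked after Peg3 (3.36 log2), Mest (1.84) and Grb10 (2.42) were seen to rise, the median was 0.04 log2 at percentile 74.06, so the rise was not found among these 25. Only 8 of them were at or above the median level of all genes on both replicate 2 arrays, and dim genes may show less change. Of 20 genes of the ERK early response left after Fosl1, Dusp5 and Plaur, the median was 0.01 log2 at percentile 58.01, so no lower expression was found there either.

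The macrophage markers that were higher in replicate 1 of both days may come from myeloid cells, since 12 microglia markers not looked at before lay at percentile 100 of matched lists on both days. The matched lists hold random genes of like level, so this does not tell microglia of the brain from other macrophages. None of the 12 is in the macrophage list, of which Ptprc (−0.32 log2 on day 0, −0.76 on day 15) and Adgre1 (−0.25 and −0.16) went the other way, and 3 of the 12 were at or above the median level of all genes on both replicate 2 arrays. Differentiation between the days would not raise replicate 1 at day 0, where the macrophage list's median gap was already 1.58 log2, against 1.49 at day 15. These values argue against it as the cause of the gap. Within a replicate number the list's median change was at most −0.22 log2 in size (percentile 0.05 of matched lists). Cd68, Lyz1 and Lyz2 were higher at day 15 within both numbers, so a change of these genes between days stays open. Whole brain RNA stays open: neuron markers had a median replicate 1 excess of at most 0.0923 log2, but the myelin genes Mbp (2.83 log2 on day 0, 2.81 on day 15) and Mobp (2.40 and 2.67) were higher in replicate 1, and the astrocyte list (3 of its 15 genes in lists fixed beforehand; 0.49 log2 between days) was higher by 0.23 and 0.31, at percentiles 99.45 and 99.72. The oligodendrocyte list's medians were 0.05 and 0.21 log2 and those of other leukocytes −0.06 and −0.11, and how such RNA entered was not tested.

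The gap of Lum and Dcn between the day 0 arrays could come from day 15 RNA in the day 0 replicate 2 array, which would take 9.77% of its RNA for Lum. That share predicts a median rise of 1.70 log2 in 18 other genes, picked as at least 4 log2 higher at day 15 than in day 0 replicate 1. The median rise observed was 0.0915, with a 75% quartile of 0.43, and 0 of the 18 reached the predicted rise. These values argue against day 15 RNA as the source. Fmod (1.12 log2), Ucma (1.00) and Igfbp4 (0.95) rose the most, so the gap was not confined to Lum and Dcn. A different growth state of the day 0 samples stays open, since the cell cycle list differed between them at percentile 100 (median 0.39 log2 higher in replicate 1), but it also differed between the day 15 samples (0.23, percentile 99.97). The 20 mitosis genes, 14 of them in lists fixed beforehand, were 1.35 log2 higher in replicate 1 at day 0 and 0.34 at day 15. They differed between days by −0.94 log2 on the replicate 1 arrays and 0.12 on the replicate 2 arrays. That list was made after the data were seen, so its day 0 gap may be partly picked. The fixed cell cycle list had a median difference between days of −0.50 log2 on the replicate 1 arrays and −0.18 on the replicate 2 arrays. This leaves the lower cell cycle list at day 15 resting in part on day 0 replicate 1.

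The higher interferon list at day 15, not called with an estimated correlation (camera adjusted p = 0.447), could follow from the myeloid RNA of replicate 1 or from scaling. Between the replicate 2 arrays, where C1qb and Csf1r were low on both days, the list lay at percentile 99.96 of lists matched on level. Over all arrays it lay at percentile 99.99 of such lists, which scaling would move alike. The 99.96 and 99.99 argue, if weakly, against these explanations as the whole cause. Within day 15 the list was 0.23 log2 higher in replicate 1 than in replicate 2, at percentile 98.1, and within day 0 it lay at 31.62. A high percentile of this list therefore also arose without a change of day. Laptm5 (6.55 and 8.56), Lyz2 (8.88 and 10.38) and Cd68 (8.10 and 9.24) were higher at day 15 on the replicate 2 arrays, so other myeloid RNA there stays open. A response of the differentiating cells stays open as a hypothesis and was not tested further.

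The 4 arrays make 3 splits into pairs, too few for a share under 0.05. The split by day called 342 genes, 1 of the 3 splits gave as many, and the highest of the others was 0, with 1666 and 123 genes at an unadjusted p below 0.05 in those others by limma.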
